A study of Arabidopsis thaliana with 24 samples.

How the data were processed

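Messenger RNA was measured by RNA sequencing in whole 9-day-old seedlings of Arabidopsis thaliana. Per the labels' protocols, total RNA was extracted, poly(A) RNA was selected, libraries were made with a TruSeq kit and sequencing was done on a HiSeq Xten instrument. The labels name 4 genotypes, WT, pkl, pif4 and pklpif4, with 3 biological replicates each, and 2 growth conditions.

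Per the submitters' processing notes, the tools were fastp, HISAT2 2.1.0 and SAMtools 1.6, and the genome build was TAIR10. The counting program, its strand setting and its treatment of reads that match several places are not given in the sources used here. The authors deposited a table of raw counts per gene, which per the file headers also holds the exon positions and the exon length of each gene. The authors also deposited a table of FPKM, in which counts are scaled by that length and by the library total. Recomputing FPKM from the counts gave the deposited values to within 4.35e-07. The count table lists 33612 genes, of which 26722 had at least 1 count. Of its identifiers, 28932 were matched to the reference annotation (assembly TAIR10.1), which was used for gene names and gene types only. Positions are those of the deposited count table, on TAIR10, and run from the first to the last exon base.

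The tables given for the samples in continuous red light were compared with those whose columns carry the number 28, read here as 28 °C in white light. Of 403344 counts and 403344 FPKM values, 0 differed, and the column names of the red-light tables name both conditions. Only the tables named for 28 were used. The red-light samples and every comparison of the growth conditions were not analysed here, and the growth condition of the libraries used rests on the column names alone.

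Low counts were mostly even. Among counts of 1 to 8, 70.9% to 74.3% per library were even, against 49.9% of counts over 100, as when both reads of a pair are counted. An alternative with halved counts was therefore added after seeing the data, and 3 fragments, or 6 counts over a group's 3 libraries, were taken as the floor. Against a group with 0 counts, a fold change is given as a lower bound computed at that floor. Against a group with 1 to 6 counts, the ratio of normalised counts is given with its exact 95% binomial interval. Such intervals and floors cover counting error only. The intervals and bounds were computed on summed counts halved to fragments and rounded up, while the ratios use the counts themselves. There were 113 genes, in 54 groups, whose 12 counts equalled those of another gene. Many of them were overlapping gene models, such as PAO2 and AT2G43018, and some with totals of 10 or 12 counts lay apart.

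Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (minimum count 10, minimum total 15) entered 1 model of group means over the 12 libraries, with TMM factors and the robust quasi-likelihood test, and 22130 genes were tested. The Benjamini-Hochberg adjusted p threshold was 0.05. Normalised CPM (counts scaled to the library total) use the TMM factors. The SE of a log2 change is its size divided by the square root of the quasi-likelihood F statistic. It is not a value that edgeR reports, and where a group has few counts it can fall below the counting error. The interaction is the effect of pkl in the pif4-labelled background (pklpif4-labelled against pif4-labelled libraries) minus its effect in WT, on the log2 scale. Gene lists were tested against all other tested genes with limma 3.58.1 camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the 21 lists of a comparison. The tests of genes and of lists were two-sided. The permutation test of neighbouring genes was one-sided, for correlations above those of permuted orders.

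These 21 lists, the tests of genes, the list tests of each mutant against WT, most alternatives and the rule for the genes named were fixed before the data were examined. List tests of the pklpif4-labelled libraries against pkl and against the pif4-labelled ones and of the interaction, and the comparison of the pif4-labelled effect between backgrounds, were added after the data were seen, as was the record of each list's call under RLE factors, the filter at 5 CPM, library totals, halved counts, the block and each library left out. The lists cover PIF4-dependent growth, auxin, expansins and xyloglucan enzymes, brassinosteroid, gibberellin, the seed and embryo programme, photosystem antenna with the Rubisco small subunit, chlorophyll, photoreceptors, flavonoids, heat shock, the circadian clock, flowering, salicylic acid, jasmonate, glucosinolates, abscisic acid and cold, root and root hair markers, stomatal lineage and trichome markers, the mitotic cell cycle and chromatin regulators. Some genes stand in more than 1 list, such as IAA19, IAA29, EXPA8, XTH15 and CYP79B2. For each mutant against WT, the genes named are the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, and up to 4 members of each list by adjusted p. For the pklpif4-labelled libraries against pkl and against the pif4-labelled ones, the same genes and up to 3 in each direction by the same rule are named. For the interaction, the 4 genes with the largest values past the threshold and a mean of at least 5 CPM are named. PKL and PIF4 are given first. Other members are named where a count of 5 or fewer called for it or as examples, and these were chosen after their values were seen.

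Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter at a mean of 5 CPM, an added 2-fold threshold, limma-trend on log2(FPKM + 1), only the libraries of the groups compared, the replicate number as a block, each library left out in turn, camera with an estimated correlation and fry. Library totals without TMM factors, and halved counts, were added after seeing the data.

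The tests were checked on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed in pkl against WT and 21387 genes tested. For 50 genes at each size, edgeR called 66% at 1.25-fold, 86% at 1.5-fold, 100% at 2-fold and 98% at 4-fold. It called 14 of 21187 unchanged genes, and 0 genes in a simulated pif4 against WT without change, where 21387 genes were tested. Of 50 simulated interactions of 2-fold it called 94%. The changed genes were drawn only from genes above a minimum mean CPM in WT. The shares called therefore do not cover genes near the floor in WT. In a separate simulated pkl against WT with 21412 genes tested, camera and fry both called a planted list of 13 genes changed 1.5-fold, and camera called 0 of the other 20 lists. At 2-fold and 4-fold, DESeq2 called 98% and 100% (22130 genes) and limma-trend 98% and 98% (21387 genes). Simulated genes were drawn independently, while the photosystem list had an estimated correlation of 0.206 in pkl against WT. The simulation therefore does not show how often lists of correlated genes are called wrongly. Its 200 changed genes were balanced in direction and far fewer than the 11858 called in pkl, so it does not check the scaling under such wide changes.

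Library totals ran from 37762216 to 56492669 counts, at which 3 fragments in 1 library equal 0.162 to 0.109 CPM. The common dispersion was 0.00233, a biological coefficient of variation of 4.83%. Replicates of a genotype differed by 3.37 to 4.15 per gene in a chi-square comparison of their counts, where sampling noise alone gives about 1, or up to about 2 if both reads of each pair were counted, so no pair was taken as 1 library deposited 2 times.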

Results

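Gene expression was compared among whole 9-day-old Arabidopsis thaliana seedlings labelled with 4 genotypes, the wild type (WT), pkl, pif4 and pklpif4, the last by its label with both mutations. PKL encodes a chromatin remodeller of the CHD3 family that keeps seed genes silent after germination. PIF4 encodes a bHLH transcription factor that promotes elongation growth in warm conditions and under low phytochrome activity. The series title concerns histone H3K4 methylation and the spatial distribution of loci. The expression data show which transcripts differ among the labelled genotypes. Each mutation cannot be told apart from other differences between the plants so labelled. There were 3 biological replicates per genotype. Total counts per library were 37762216 to 56492669 in WT, 41220985 to 52980805 in pkl, 40168802 to 47237160 in the libraries labelled pif4 and 38675068 to 48991932 in those labelled pklpif4. The libraries carried the number 28 in their names, and their growth condition rests on those names alone, since the red-light tables held the same values and were not used here. The first 3 principal components held 48.1%, 21.7% and 13.0% of the variance, and the fourth held 2.81%.

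PKL (AT2G25170; chromosome 2, 10713807 to 10723986) had 97.3 ± 4.12 CPM in WT (mean ± SD, n = 3, as for all values below), 103 ± 4.03 in pkl, 91.8 ± 3.34 in the pif4-labelled and 104 ± 2.64 in the pklpif4-labelled libraries. The change in pkl was 0.08 ± 0.04 on the log2 scale (± SE; adjusted p = 0.0547, edgeR), and it passed with RLE factors, both other filters, limma-trend, library totals, halved counts or without WT replicate 3 (log2 0.11) or pkl replicate 1 (0.10). The PKL transcript therefore neither supports nor contradicts the pkl label. PIF4 (AT2G43010; chromosome 2, 17886427 to 17889050) had 100.4 ± 4.56 CPM in WT and fell to 65.8 ± 2.97 in pkl (log2 -0.61 ± 0.03, adjusted p = 2.33e-31). It rose to 174 ± 3.36 CPM in the pif4-labelled libraries (log2 0.79 ± 0.03, adjusted p = 8.02e-42) and was 148 ± 1.09 CPM in the pklpif4-labelled ones. A loss of the PIF4 transcript would lower its count, which rose instead, but a count alone does not decide the pif4 label. Genes that depend on PIF4, given below, were lower in the pif4-labelled libraries (median log2 change -1.61). These libraries are named by their labels throughout, and directions drawn from them rest on the labels. The next gene on the chromosome, the polyamine oxidase gene PAO2 (AT2G43020; chromosome 2, 17891503 to 17894635), rose with PIF4, from 24.4 ± 3.04 CPM in WT to 159 ± 5.04 in the pif4-labelled libraries (log2 2.70 ± 0.06, adjusted p = 1.67e-21). It was 27.7 ± 2.52 CPM in pkl and 122 ± 3.42 in the pklpif4-labelled libraries. Its counts equalled those of the overlapping AT2G43018, and the reads of these genes cannot be told apart.

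**Figure D1:**
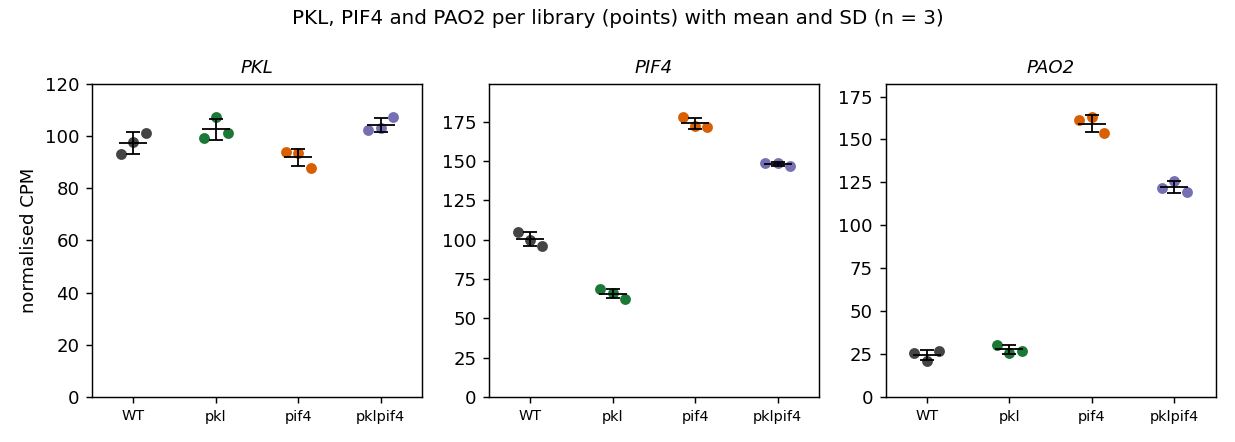
Normalised CPM (linear axis from 0) of PKL, PIF4 and PAO2 in each library of the 4 genotypes; points are libraries, bars the mean and SD of 3. PIF4 and PAO2 were higher in all libraries labelled pif4 and pklpif4 than in WT and pkl, while PKL lay between 87.9 and 107 CPM in all 12.

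In pkl, seed genes, jasmonate genes and root and root hair markers were higher than in WT, and photosystem, chlorophyll and glucosinolate genes were lower. Of 20 tested seed and embryo genes, 13 rose and 2 fell, with a median log2 change of 1.66 (camera adjusted p = 0.00358, and adjusted p = 0.0251 with an estimated correlation). On log2(FPKM + 1) the median was 0.57. Some members lay near the floor, such as SESA1 and SESA4, with 0 counts in WT and 82 and 43 in pkl. PER1, a seed peroxiredoxin, rose from 3.12 ± 0.527 to 15.3 ± 0.744 CPM (log2 2.31 ± 0.09). The oil body gene OLEO2 rose from 0.920 ± 0.229 to 5.23 ± 0.0623 CPM, and the storage albumin gene SESA2 from 0.0520 ± 0.0510 to 1.48 ± 0.253. The 2 members that fell were storage protein genes, CRU3, from 16.7 ± 0.731 to 1.13 ± 0.280 CPM (log2 -3.89 ± 0.07), and SESA5, from 1.05 ± 0.325 to 0.443 ± 0.162. The call of this list was lost with a filter at a mean of 5 CPM (adjusted p = 0.0506) and with halved counts (adjusted p = 0.0576). LEC1, LEC2 and FAE1 had too few counts to be tested, and the tandem copies SESA1 to SESA4 are similar in sequence, so their separate values are uncertain.

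Jasmonate genes rose in 8 of 13 cases and fell in 2, VSP1 and TAT3 (median 0.31; adjusted p = 2.48e-06, and adjusted p = 0.00852 with an estimated correlation). Among them were the synthesis genes LOX2 (log2 1.56 ± 0.03) and AOC2 (2.34 ± 0.06), the transcription factor gene MYC2 (1.09 ± 0.05) and the repressor gene JAZ1 (1.38 ± 0.08). Root and root hair markers rose in 11 of 16 cases and 1, SHR, fell (median 1.00; adjusted p = 1.93e-05, and adjusted p = 0.0077 with an estimated correlation). The root hair wall genes PRP3, EXPA7 and COBL9 rose by 1.93 ± 0.06, 2.06 ± 0.11 and 2.14 ± 0.18.

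All 19 photosystem and Rubisco small subunit genes fell in pkl (median -0.46; adjusted p = 4.48e-31, and adjusted p = 0.00363 with an estimated correlation). LHCA4 went from 3049 ± 41.4 to 1882 ± 20.2 CPM (log2 -0.70 ± 0.02) and LHCA1 fell by 0.86 ± 0.02 on that scale. Of 13 chlorophyll synthesis genes 12 fell (median -0.34; adjusted p = 3.3e-09, and adjusted p = 0.00334 with an estimated correlation), among them the protochlorophyllide reductase gene PORC (-0.83 ± 0.04) and the magnesium chelatase gene GUN5 (-0.33 ± 0.01). The markers of root, another organ in these whole seedlings, were higher in the same libraries. Of 13 glucosinolate genes, 9 fell and 3 rose (median -0.74; adjusted p = 0.000302, and adjusted p = 0.0168 with an estimated correlation). The falls held genes of the aliphatic branch, CYP79F1 (-2.19 ± 0.11), CYP83A1 (-1.25 ± 0.05), MAM1 (-1.38 ± 0.05) and their regulator MYB29 (-2.49 ± 0.15). CYP79B3, of the indolic branch, also fell. The 3 that rose were CYP79B2 and CYP83B1, of the indolic branch, and CYP79F2, whose counts are uncertain since it is a near copy of CYP79F1.

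In 3 further lists, lower in pkl, the call rested on the preset correlation and was lost under several alternatives. Of 15 flowering genes 8 fell and 1, MAF4, rose (median -0.51; adjusted p = 0.0466, and adjusted p = 0.196 with an estimated correlation), with SEP3 at -1.87 ± 0.18, FLC at -1.26 ± 0.17 and PI at -1.42 ± 0.19. FUL fell from 0.941 ± 0.311 to 0.0158 ± 0.0273 CPM, a ratio of 67.4-fold (95% interval 11.8 to 2723). Of 11 mitotic genes 7 fell and 0 rose (median -0.47; adjusted p = 0.0466, and adjusted p = 0.122 with an estimated correlation), with CYCD3;1 at -0.77 ± 0.07. Of 17 expansin and xyloglucan genes 9 fell and 6 rose (adjusted p = 0.0427, and adjusted p = 0.215 with an estimated correlation). EXPA8 fell by 1.43 ± 0.05, but the list's median of -0.06 turned to 0.00301 with library totals in place of TMM factors. Over 17 alternatives, libraries left out in turn included, adjusted p ran from 0.0199 to 0.509 for flowering, from 0.014 to 0.139 for mitotic genes and from 0.0273 to 0.141 for expansins. Flowering and mitotic genes were lost without each of the 3 pif4-labelled libraries in turn (adjusted p of 0.0537, 0.0569 and 0.0652, and of 0.0629, 0.066 and 0.0652), and mitotic genes also without pkl replicate 3 (0.0584). Both were also lost with the filter at 5 CPM (0.509 and 0.139) and with halved counts (0.095 and 0.0855). Expansins were lost with library totals (0.0509) and halved counts (0.0533), and without WT replicate 1 (0.0612), pkl replicate 3 (0.0676) or pklpif4-labelled replicate 3 (0.0556).

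The other 12 lists did not pass in pkl, with adjusted p from 0.0842 for stomatal and trichome markers to 0.943 for salicylic acid. Of the stomatal and trichome genes 9 of 12 fell and 3 rose, TMM at -1.26 ± 0.10 and TRY at -2.58 ± 0.38, and the list had an adjusted p of 0.215 with an estimated correlation and, with the preset one, passed in 3 of 17 alternatives, among them library totals (adjusted p = 0.0398) and the fit without pkl replicate 2 (0.0445). Counts of genes higher and lower were 7 and 12 of 22 for PIF4-dependent growth, 9 and 5 of 21 for auxin, 1 and 5 of 10 for brassinosteroid, and 3 and 4 of 15 for gibberellin. They were 2 and 5 of 15 for photoreceptors, 1 and 1 of 11 for flavonoids, 3 and 4 of 17 for heat shock, and 5 and 4 of 12 for the clock. They were 2 and 1 of 11 for salicylic acid, 3 and 6 of 12 for abscisic acid and cold, and 1 and 7 of 17 for chromatin regulators, among which the CHD3 homologue PKR1 fell by 0.55 ± 0.04 on the log2 scale. Adjusted over the list alone, these counts were the same except for flavonoids (0 and 1), salicylic acid (1 and 1), root markers (12 and 1) and mitotic genes (0 and 9).

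The largest rises in pkl were of loci almost silent in WT. The noncoding RNA gene AT2G01422 (chromosome 2, 183940 to 184734) went from 0.0301 ± 0.0275 to 68.4 ± 2.51 CPM, a ratio of 2256-fold (95% interval 624 to 18634), and AT4G29200 from 0.0230 ± 0.0258 to 42.0 ± 1.13 CPM. AT3G01345 rose to 109.9 ± 0.458 CPM (log2 8.68 ± 0.10), AT3G23060 to 15.1 ± 0.379 and AT3G42658.1 to 16.6 ± 1.43. The largest falls were AT5G43800.1, from 41.5 ± 1.63 to 0.111 ± 0.0894 CPM, AT5G35935.1 (-4.73 ± 0.14), the immune-related AIG1 (-4.48 ± 0.34), AT1G66100 (-4.45 ± 0.17) and the receptor-like protein gene RLP19 (-4.03 ± 0.16). In all, 11858 of 22130 genes passed the edgeR threshold in pkl, 5993 higher and 5865 lower. Of these, 2411 changed at least 2-fold, 1762 higher and 649 lower. The share of higher genes among those called was 50.5%, and 62.0% with library totals in place of TMM factors.

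In the pif4-labelled libraries, the genes known to need PIF4 for growth were lower than in WT, and auxin, heat shock, jasmonate and abscisic acid genes were lower with them. Of 22 PIF4-dependent genes, 19 fell and 1 rose, with a median log2 change of -1.61 (camera adjusted p = 1.38e-29, and adjusted p = 5.19e-05 with an estimated correlation). HFR1 fell from 85.2 ± 2.56 to 12.7 ± 0.239 CPM (log2 -2.75 ± 0.06), the sulfotransferase gene ST2A from 31.6 ± 1.04 to 3.82 ± 0.719 and the homeobox gene HB-2 from 35.1 ± 1.49 to 11.7 ± 1.11. CYP79B2 was the member that rose (0.27 ± 0.06). The members SAUR19 to SAUR24 are near copies of each other, so their separate counts are uncertain.

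Auxin response genes fell in 15 of 21 cases and rose in 3 (median -0.76; adjusted p = 4.78e-09, and adjusted p = 0.00106 with an estimated correlation), with IAA29 at -3.25 ± 0.18 and GH3.5 at -1.27 ± 0.04. Heat shock genes fell in 14 of 17 cases (median -1.48; adjusted p = 1.3e-06, and adjusted p = 0.00753 with an estimated correlation). The small heat shock protein genes HSP17.6A and HSP17.6C fell by 3.23 ± 0.22 and 3.87 ± 0.30 on the log2 scale, and HSFA7A was the member that rose (0.90 ± 0.10). With a filter at a mean of 5 CPM the heat shock call was lost (adjusted p = 0.186). Jasmonate genes fell in 10 of 13 cases (median -0.93; adjusted p = 2.58e-07, and adjusted p = 0.00375 with an estimated correlation), LOX2 at -1.24 ± 0.03 and VSP2 at -1.12 ± 0.10, and MYC2 rose by 0.41 ± 0.05. Abscisic acid and cold genes fell in 9 of 12 cases (median -0.56; adjusted p = 2.06e-06, and adjusted p = 0.00375 with an estimated correlation), with HAI1 at -1.26 ± 0.08 and the abscisic acid synthesis gene NCED3 at -1.20 ± 0.13.

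All 16 tested root and root hair markers rose in the pif4-labelled libraries (adjusted p = 1.36e-12, and adjusted p = 0.000939 with an estimated correlation). The iron uptake genes IRT1 and FRO2 rose from 14.6 ± 0.681 to 50.1 ± 3.16 CPM and from 6.96 ± 0.501 to 26.0 ± 1.09 CPM. In the same libraries, 17 of 19 photosystem genes fell (median -0.27; adjusted p = 1.07e-19, and adjusted p = 0.0056 with an estimated correlation), LHCB3 at -0.61 ± 0.02, and RBCS1B rose. Of 13 chlorophyll genes 9 fell and 1, CHLM, rose (median -0.14; adjusted p = 0.00594, and adjusted p = 0.0313 with an estimated correlation), HEMA1 at -0.24 ± 0.02, and the call was lost with the filter at 5 CPM (adjusted p = 0.0603). Glucosinolate genes fell in 9 of 13 cases (median -0.46; adjusted p = 2.09e-06, and adjusted p = 0.00671 with an estimated correlation), CYP79F1 at -1.86 ± 0.11. The calls of 2 lists were lost with an estimated correlation. These were expansins and xyloglucan enzymes, 11 lower and 3 higher of 17 (adjusted p = 0.000754, and adjusted p = 0.076 with an estimated correlation), and photoreceptors, 7 lower and 2 higher of 15 (adjusted p = 0.0414, and adjusted p = 0.076 with an estimated correlation), with PHYB at -0.59 ± 0.03. The photoreceptor call was also lost with the filter at 5 CPM (adjusted p = 0.186), library totals (0.0617) or halved counts (0.0518), and without WT replicate 2 (adjusted p = 0.0557) and without each pif4-labelled library (0.0526, 0.0592 and 0.0682).

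The other 10 lists did not pass, with adjusted p from 0.0542 for the clock, where 6 genes were higher and 1 lower of 12, to 0.695 for stomatal and trichome markers. The clock list had an adjusted p of 0.136 with an estimated correlation and, with the preset one, passed as higher in 9 of 17 alternatives, among them the fits without WT replicate 1 (adjusted p = 0.0383), without each pkl library (0.0422, 0.0427 and 0.047) and without each pklpif4-labelled library (0.0413, 0.045 and 0.0363). For the seed and embryo list, 6 of 20 genes rose and 2 fell (adjusted p = 0.177, and adjusted p = 0.201 with an estimated correlation), with PER1 at 1.83 ± 0.09 and CRU3 at -3.30 ± 0.07. Adjusted over the list alone, counts of higher and lower genes differed for chlorophyll (2 and 9), photoreceptors (2 and 8), glucosinolates (3 and 10), stomatal markers (0 and 0) and mitotic genes (0 and 4).

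The largest rises were of AT2G28780 (2.97 ± 0.15), the fatty acid desaturase gene FTM1 (2.87 ± 0.22), PAO2 with AT2G43018, and the myrosinase gene BGLU35 (2.54 ± 0.11). AT5G43800.1 had 41.5 ± 1.63 CPM in WT and 0 counts in the pif4-labelled libraries, at least 928-fold lower. The other large falls were AT4G12490 (a ratio of 2263-fold (95% interval 406 to 89409.9)), the acetyltransferase gene NATA1 (717-fold (95% interval 149 to 4447)), ELI3-2 (-8.21 ± 0.23) and AT2G38240 (-7.85 ± 0.20). In all, 7184 genes passed, 3590 higher and 3594 lower, and 1375 changed at least 2-fold, 859 higher and 516 lower. With library totals, 61.2% of the genes called were higher.

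In the pklpif4-labelled libraries, seed storage and late embryo genes reached levels far above those of the other 3 genotypes. Of 20 tested seed and embryo genes, 17 rose against WT and 0 fell, with a median log2 change of 6.27, or 6.05 with genes at the floor set to their bound (camera adjusted p = 6.9e-136, and adjusted p = 6.26e-06 with an estimated correlation). Summed over the list, these genes made up 60.8 ± 0.792 CPM in WT, 80.4 ± 3.34 in pkl, 68.2 ± 1.28 in the pif4-labelled and 4279 ± 19.9 in the pklpif4-labelled libraries. The globulin gene CRA1 rose from 30.8 ± 1.33 to 1895 ± 19.7 CPM, and CRU3 from 16.7 ± 0.731 to 1192 ± 12.9 (log2 6.16 ± 0.03, adjusted p = 6.12e-125). SESA5 rose to 560.2 ± 14.1 CPM and SESA2 to 132 ± 2.37. The 3 that did not pass were FUS3, L1L and AGL15, all coding for transcription factors, with log2 values of -0.34 ± 0.39, -0.58 ± 0.77 and -0.18 ± 0.19.

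**Figure D2:**
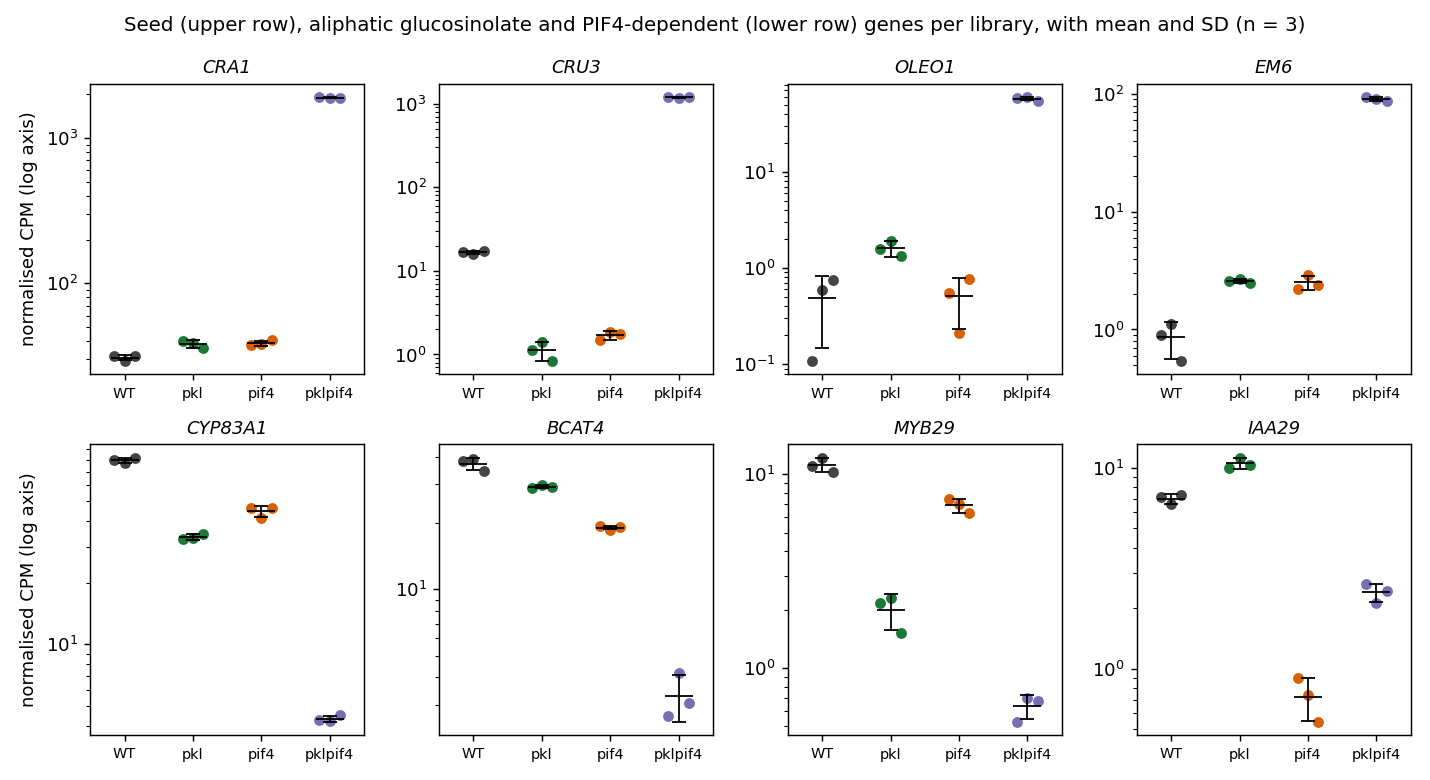
Normalised CPM (log axes) per library of 4 seed genes, 3 aliphatic glucosinolate genes and IAA29, a PIF4-dependent auxin gene, in the 4 genotypes; points are libraries, bars the mean and SD of 3. The pklpif4-labelled libraries stand above the others in CRA1 (1895 CPM against 30.8 in WT) and below them in CYP83A1 (4.32 against 79.5).

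Glucosinolate genes fell in 11 of 13 cases in the pklpif4-labelled libraries (median -2.50; adjusted p = 3.14e-23, and adjusted p = 0.000588 with an estimated correlation). MAM1 went from 103 ± 2.29 to 5.81 ± 0.479 CPM, CYP83A1 from 79.5 ± 2.45 to 4.32 ± 0.141, BCAT4 from 37.2 ± 2.47 to 3.29 ± 0.780 and CYP79F1 from 24.5 ± 1.77 to 0.0805 ± 0.0658. The 2 that rose, CYP79B2 and CYP83B1, belong to the indolic branch. PIF4-dependent genes fell in 17 of 22 cases (median -1.59; adjusted p = 1.8e-11, and adjusted p = 0.00205 with an estimated correlation), HFR1 at -2.78 ± 0.06, ST2A at -2.43 ± 0.09 and XTH15 at -1.70 ± 0.06.

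In 5 further lists the call was lost with an estimated correlation. These were auxin, 14 lower and 3 higher of 21 (adjusted p = 0.0132, and adjusted p = 0.0628 with an estimated correlation), expansins, 11 and 6 of 17 (adjusted p = 0.00442, and adjusted p = 0.135 with an estimated correlation), and jasmonate, 9 and 2 of 13 (adjusted p = 0.0203, and adjusted p = 0.131 with an estimated correlation). Root markers were 13 higher and 2 lower of 16 (adjusted p = 0.0187, and adjusted p = 0.0732 with an estimated correlation), with PRP3 at 1.38 ± 0.06 and IRT1 at -2.13 ± 0.09. The abscisic acid and cold list was called higher (adjusted p = 0.0244, and adjusted p = 0.0889 with an estimated correlation) although its median was -0.41 and its mean -0.09. There RAB18 and RD29B, late embryo and drought genes, rose by 3.61 ± 0.04 and 2.81 ± 0.05, while 7 of 12 members fell, NCED3 at -2.06 ± 0.14. This call was lost without each WT library in turn (adjusted p of 0.72, 0.425 and 0.0794), without pkl replicate 1 or 2 (0.21 and 0.263) and without pklpif4-labelled replicate 1 or 3 (0.126 and 0.768). With the filter at 5 CPM, jasmonate (adjusted p = 0.254) and root markers (adjusted p = 0.334) were lost as well. The other 13 lists did not pass, with adjusted p from 0.0574 for photosystem genes to 0.79 for salicylic acid. Photosystem genes were 10 higher and 5 lower of 19 (median 0.06; adjusted p = 0.41 with an estimated correlation) and, with the preset correlation, passed as higher in 12 of 17 alternatives, with adjusted p from 0.013 without pkl replicate 1 to 0.0722. Chlorophyll genes were 8 higher and 1 lower of 13, with PORA up from 0.965 ± 0.214 to 20.8 ± 0.858 CPM. Adjusted over the list alone, only PIF4-dependent growth had other counts, 3 higher and 17 lower.

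**Figure D3:**
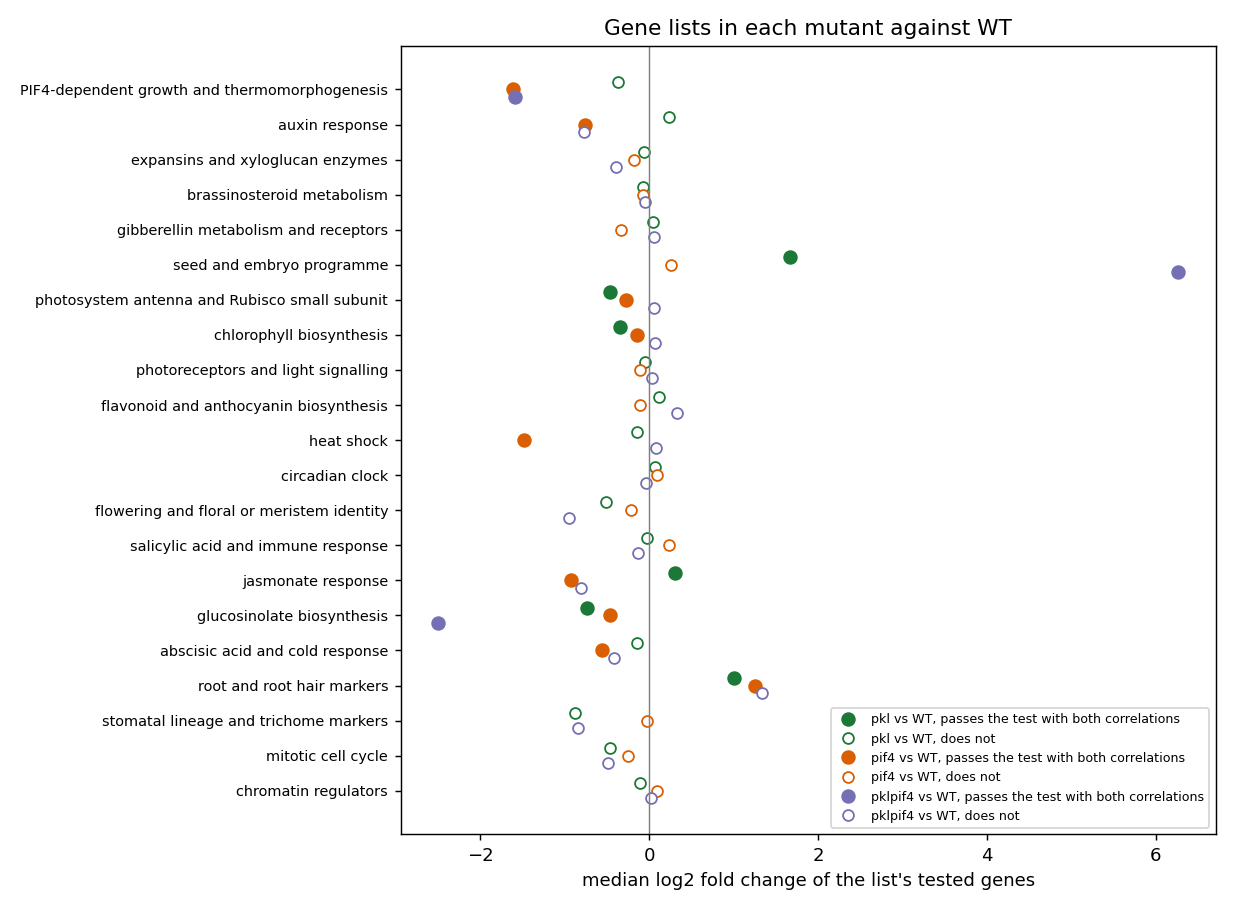
Median log2 fold change (x axis) of the tested genes of each of the 21 lists (y axis) in pkl, pif4-labelled and pklpif4-labelled libraries against WT. Filled points passed camera with both the preset and the estimated correlation; the seed list stood at 1.66, 0.26 and 6.27 in the 3 comparisons.

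AT3G22490, a late embryo gene, and SESA1 had 0 counts in WT and were at least 425-fold and at least 404-fold higher in the pklpif4-labelled libraries, and AT2G01422 was higher by a ratio of 2253-fold (95% interval 623 to 18609). AIG1 had 0 counts in the pklpif4-labelled libraries, at least 111-fold lower than WT. AT5G43800.1 was lower by a ratio of 2745-fold (95% interval 492 to 108479), AT2G38240 by 933-fold (95% interval 258 to 7711) and AT4G12490 by 744-fold (95% interval 254 to 3609). In all, 12136 genes passed against WT, 6009 higher and 6127 lower, and 2857 changed at least 2-fold, 1825 higher and 1032 lower.

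Against pkl, the pklpif4-labelled libraries had higher seed, photosystem and chlorophyll genes and lower PIF4-dependent, auxin, jasmonate and glucosinolate genes. Seed genes rose in 16 of 20 cases and 1, L1L, fell (median 4.16; adjusted p = 2.97e-68, and adjusted p = 1.43e-06 with an estimated correlation). CRU3 went from 1.13 to 1192 CPM (log2 10.05 ± 0.05). All 19 photosystem genes rose (median 0.54; adjusted p = 3.67e-51, and adjusted p = 0.000342 with an estimated correlation), CAB2 by 1.05 ± 0.02, and all 13 chlorophyll genes rose (median 0.37; adjusted p = 4.84e-19, and adjusted p = 0.000117 with an estimated correlation). Root markers were 6 higher and 5 lower of 16 here (adjusted p = 0.281, and adjusted p = 0.349 with an estimated correlation). Jasmonate genes fell in 12 of 13 cases (adjusted p = 3.47e-20, and adjusted p = 0.000147 with an estimated correlation), LOX2 at -1.51 ± 0.03. All 13 glucosinolate genes fell (adjusted p = 7.74e-19, and adjusted p = 0.000605 with an estimated correlation), CYP83A1 at -2.95 ± 0.07. PIF4-dependent genes fell in 18 of 22 cases (adjusted p = 2.5e-12, and adjusted p = 0.000717 with an estimated correlation) and auxin genes in 15 of 21 (adjusted p = 3.07e-08, and adjusted p = 0.000717 with an estimated correlation).

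Heat shock genes, 9 higher and 6 lower of 17, passed only with the preset correlation (adjusted p = 0.0382, and adjusted p = 0.153 with an estimated correlation), with a median of 0.24 and a mean of -0.05. The call was lost without pif4-labelled replicate 1 or 2 (adjusted p of 0.057 and 0.0559), pkl replicate 3 (0.0788) or pklpif4-labelled replicate 3 (0.0604). The other 13 lists had adjusted p from 0.0828 for abscisic acid to 0.899 for the clock. The abscisic acid and cold list had 4 genes higher and 7 lower of 12, a median of -0.41 and a mean of 0.26 (adjusted p = 0.151 with an estimated correlation). The camera test called it higher with halved counts (adjusted p = 2.14e-05) and without WT replicate 3 (0.0118) or each pif4-labelled library in turn (2.11e-05, 2.47e-05 and 0.02). Adjusted over the list alone, counts of higher and lower genes differed for auxin (0 and 16), gibberellin (1 and 3), seed (17 and 1), jasmonate (0 and 13), root (6 and 6), stomatal markers (1 and 2) and mitotic genes (0 and 0). MLP31 and AT1G14950 had 0 counts in pkl and were at least 426-fold and at least 136-fold higher, and the late embryo gene ATECP31 was higher by a ratio of 2308-fold (95% interval 639 to 19066). The largest falls were AT2G38240 (a ratio of 323-fold (95% interval 89.3 to 2678)), NATA1 (-8.04 ± 0.24) and ELI3-2 (-7.21 ± 0.20). In all, 8840 genes passed, 4312 higher and 4528 lower, and 1410 changed at least 2-fold. The share of higher genes was 48.8%, and 37.4% with library totals.

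Against the pif4-labelled libraries, those labelled pklpif4 had higher seed, photosystem, chlorophyll and heat shock genes and lower glucosinolate genes. Seed genes rose in 17 of 20 cases (median 5.56; adjusted p = 4.82e-87, and adjusted p = 5.65e-06 with an estimated correlation). Photosystem genes rose in 18 of 19 (adjusted p = 2.15e-18, and adjusted p = 0.0107 with an estimated correlation), chlorophyll genes in 11 of 13 (adjusted p = 0.00028, and adjusted p = 0.0109 with an estimated correlation) and heat shock genes in 10 of 17 (adjusted p = 6.74e-06, and adjusted p = 0.0109 with an estimated correlation). HSP17.6A went from 0.283 ± 0.0229 to 28.5 ± 1.07 CPM. The abscisic acid and cold list was called higher (adjusted p = 6.72e-06, and adjusted p = 0.00648 with an estimated correlation), with 4 of 12 genes higher, 2 lower and 6 not passing, a median of 0.10 and a mean of 0.51. Glucosinolate genes fell in 11 of 13 (adjusted p = 1.14e-17, and adjusted p = 0.000699 with an estimated correlation). The clock (adjusted p = 0.027, and adjusted p = 0.112 with an estimated correlation) and stomatal and trichome lists (adjusted p = 0.0359, and adjusted p = 0.124 with an estimated correlation) passed as lower only with the preset correlation, and both were lost without WT replicate 3 (adjusted p of 0.0522 and 0.0642) or pif4-labelled replicate 1 (0.0553 and 0.0553). The stomatal list was also lost without pif4-labelled replicate 2 or 3 (0.0511 and 0.0708), with halved counts (0.084) and with the filter at 5 CPM (0.156). The other 13 lists did not pass, among them the PIF4-dependent list with 8 genes higher and 4 lower of 22 (adjusted p = 0.591, and adjusted p = 0.586 with an estimated correlation). Counts adjusted over the list alone were the same except for PIF4-dependent growth and thermomorphogenesis (9 and 4) and brassinosteroid metabolism (3 and 4) and flavonoid and anthocyanin biosynthesis (2 and 1) and flowering and floral or meristem identity (2 and 8) and abscisic acid and cold response (5 and 3) and stomatal lineage and trichome markers (0 and 9) for this comparison.

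ATECP31, SESA1 and MLP31 had 0 counts in the pif4-labelled libraries and were at least 1483-fold, at least 413-fold and at least 411-fold higher in the pklpif4-labelled ones. AT5G37990 was at least 157-fold lower, and RLP19 and CYP79F1 changed by -6.47 ± 0.24 and -6.43 ± 0.24. In all, 11099 genes passed, 5636 higher and 5463 lower, and 2069 changed at least 2-fold.

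The interaction asked whether the changes in pkl and in the pif4-labelled libraries added up on the log2 scale. For seed, photosystem, chlorophyll and heat shock genes the pklpif4-labelled libraries lay above the sum of these changes, and for glucosinolate, jasmonate and root genes below it. All 19 photosystem genes and all 13 chlorophyll genes had a positive interaction, with medians of 0.80 (adjusted p = 6.79e-77, and adjusted p = 0.000152 with an estimated correlation) and 0.54 (adjusted p = 8.66e-25, and adjusted p = 7.97e-05 with an estimated correlation). CAB2 was 3246 ± 12.2 CPM in WT, 2176 ± 79.4 in pkl, 2509.6 ± 28.7 in the pif4-labelled and 4508 ± 21.1 in the pklpif4-labelled libraries (interaction 1.42 ± 0.02). Seed genes were above the sum in 13 of 20 cases (median 3.89; adjusted p = 3.69e-17, and adjusted p = 0.000517 with an estimated correlation) and heat shock genes in 11 of 17 (adjusted p = 1.62e-08, and adjusted p = 0.0026 with an estimated correlation). Glucosinolate genes were below it in 11 of 13 (median -1.30; adjusted p = 6.14e-13, and adjusted p = 0.000855 with an estimated correlation), jasmonate genes in 11 of 13 (adjusted p = 2.63e-07, and adjusted p = 0.00241 with an estimated correlation) and root markers in 10 of 16 (median -1.26; adjusted p = 6.2e-10, and adjusted p = 0.00068 with an estimated correlation). IRT1, for example, was 14.6, 16.6, 50.1 and 3.35 CPM in the 4 genotypes (interaction -4.10 ± 0.12). CAB2 and IRT1 were chosen as examples after their values were seen. The PIF4-dependent (adjusted p = 0.0119, and adjusted p = 0.0433 with an estimated correlation) and abscisic acid lists (adjusted p = 2.63e-07, and adjusted p = 0.00172 with an estimated correlation) also passed, with positive medians of 0.54 and 0.27, and the other 12 lists did not. Counts adjusted over the list alone were the same except for brassinosteroid metabolism (2 and 3) and seed and embryo programme (14 and 1) and mitotic cell cycle (1 and 0) for the interaction. In all, 7054 genes had an interaction past the edgeR threshold, 3394 positive and 3660 negative, and for 1729 it was at least 1 on the log2 scale, 621 positive and 1108 negative. The share of positive values was 48.1%, and 31.1% with library totals.

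The genes changed in pkl and in the pif4-labelled libraries overlapped. Of the 5108 genes past the threshold in both, 2023 were higher in both, 1526 lower in both and 1559 went opposite ways. PER1 and PRP3 were among those higher in both and LHCA4, MAM1 and EXPA8 among those lower in both, while LOX2 and AOC2 rose in pkl and fell in the pif4-labelled libraries. Independent lists of these sizes would share 972 higher, 952 lower and 1925 opposite. The correlation across genes was 0.376, with a covariance of 0.208. Simulated unchanged groups against the same WT libraries gave 0 shared genes, a correlation of 0.496 and a covariance of 0.0146. Where no gene is changed almost none is called, so the 0 shared genes decide nothing. A correlation of noise alone is also not comparable with one across changed genes. The covariance of 0.0146 against 0.208 argues against noise in the shared WT libraries, as simulated, as the whole source. The 3 WT libraries were not divided between the comparisons, so part of the excess may come from the shared controls.

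The effect of pkl in WT and its effect in the pif4-labelled background share no library. Across the 22130 genes, which are not independent replicates, they had a Pearson r of 0.495 (Spearman rho 0.532), and 7688 genes passed in both, 6630 with the same sign. Without a low-count filter, r was 0.321. The effect of the pif4 label in WT and in the pkl background had an r of 0.253 (rho 0.188), and 4221 genes passed in both, 2864 with the same sign. Without that filter, r was 0.159. PIF4 itself was higher in both pif4-labelled comparisons (log2 0.79 ± 0.03 and 1.17 ± 0.03), as was PAO2 (2.70 ± 0.06 and 2.14 ± 0.06). LHCA1, chosen after its values were seen, went opposite ways, at -0.36 ± 0.02 in the WT and 0.86 ± 0.02 in the pkl background.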

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

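The interaction of genes was planned. The list tests of the interaction, the counts of other splits and the tests of the 3 patterns below were chosen after the results were seen, except the test that left out the most abundant genes. It decided nothing, and a test chosen afterwards took its place.

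The results listed here stood out because the effect of pkl differed between the WT and the pif4-labelled background, by the interaction test. It differed for 7054 genes. Median interactions of the lists that passed with both correlations were 0.54 for PIF4-dependent growth, 3.89 for seed, 0.80 for photosystem, 0.54 for chlorophyll, 0.72 for heat shock, -0.87 for jasmonate, -1.30 for glucosinolates, 0.27 for abscisic acid and cold, and -1.26 for root markers. The genes with the largest values were ATECP31 at 17.03 ± 1.01, SESA5 at 13.52 ± 0.31, CRU3 at 13.35 ± 0.08 and the nitrile specifier protein gene NSP2 at 11.79 ± 0.36. NSP2 had 2.00 ± 0.217 CPM in WT, 0.336 ± 0.0291 in pkl, 0.0389 ± 0.0373 in the pif4-labelled and 23.9 ± 0.725 in the pklpif4-labelled libraries. The fitted values of ATECP31, SESA5 and NSP2 depend on the prior count, since they were at or near 0 in at least 1 group, and are no bounds.

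Of 60 drawn regroupings of the 12 libraries, the real one included, 2 gave as many interaction genes as the real 7054, the highest other being 8549. For the lists with an interaction, 7 of 60 gave as many as the real 9, with a highest other of 10. For the overlap of pkl and the pif4-labelled libraries, 1 of 60 reached the real 3549 genes changed the same way, with a highest other of 3495. For the correlations between backgrounds, 8 of 60 reached 0.495 for pkl (highest other 0.744) and 19 of 60 reached 0.253 for the pif4 label (highest other 0.769). These splits mix genotypes within groups, which raised the common dispersion from 0.00233 to a median of 0.0804, and 52 of the 59 others gave 0 interaction genes and 55 gave 0 shared genes. They therefore decide nothing about chance, for or against. The comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. Every split but the real one also mixes the genotypes within groups, so these splits decide nothing about chance either. In the 5 comparisons of genotypes 1 split, the real one, gave 11858, 7184, 12136, 8840 and 11099 genes, and the highest other gave 0. For lists, 1, 1 and 2 splits gave as many as the real 9, 11 and 8 in pkl, pif4-labelled and pklpif4-labelled libraries against WT, with highest others of 8, 9 and 8.

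The seed and embryo genes were higher in the pklpif4-labelled libraries than in pkl. The list's median change stayed at 2.76 or more with RLE factors, library totals and the deposited FPKM. RLE factors and library totals move all genes alike, and the median over all genes was 0.0083 and -0.041 with them. The deposited FPKM are themselves scaled by library totals. The choice among these scalings therefore cannot account for the change, but the test could hardly have turned out otherwise and covers no other fault of the normalization. Ungerminated seeds or late embryos in the tissue could also bring storage transcripts. The summed seed genes varied by 0.464% over the 3 libraries, which describes an even level but does not decide, because no table here holds a seed of this genotype, so seed tissue and a change of expression in the seedlings cannot be told apart. The genotype as labelled stays open as a source of the change and was not tested further.

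PIF4 reads were higher in the libraries labelled pif4 than in WT. An exchange of the WT and pif4 labels is argued against, since PIF4-dependent genes had a median of -1.61 in the libraries labelled pif4, and reads of an annotated overlapping gene are too, since 0 listed genes overlap PIF4. A candidate explanation is altered transcription along the locus in the pif4 line, such as from an insertion. Of 12 tested genes within 20 kb, 3 (PAO2, AT2G43018 with the same counts, and NAC042 at about 1 CPM) were higher by at least 1 in both pif4-labelled comparisons, against 0.646% of genes genome-wide. The window was set after PAO2 was seen, so this is a hypothesis found and tested on the same data.

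Photosystem and chlorophyll genes were lower in pkl and in the pif4-labelled libraries and not in the pklpif4-labelled libraries. The lower of the median interactions of the photosystem and chlorophyll lists stayed at 0.45 or more with RLE factors, library totals and the deposited FPKM. RLE factors and library totals moved the median interaction over all genes only to -0.0019 and -0.084. The choice among these scalings therefore cannot account for the pattern, but the test could hardly have turned out otherwise and covers no other fault of the normalization. A few genes taking most of the counts would shift all other genes alike. With library totals, the lower of the photosystem and chlorophyll list medians lay 0.54 above the median over all tested genes. These lists were flagged because they had passed against all other genes. The value therefore restates that result and is no separate test of such a shift. Leaving the 100 most abundant genes out of the scaling moved the median over all genes by at most 0.010 and decides nothing. A larger share of root in the seedlings could lower leaf transcripts, and root markers were higher in pkl and in the pif4-labelled libraries. They were also higher in the pklpif4-labelled libraries, with a median of 1.34 against WT, where the photosystem genes were not lower, which root share as the whole cause would not give. That test and its bounds were written with the value known. The camera call of the root list in those libraries did not hold with an estimated correlation (adjusted p = 0.0732) or with the filter at 5 CPM (0.334). With that filter, root markers were called lower there than in pkl (adjusted p = 0.024) and in the pif4-labelled libraries (0.033). The root interaction, with a median of -1.26, ran opposite to that of the photosystem genes. The values go both ways, and root share is left open. The genotype as labelled stays open as a source, and other differences in tissue or developmental stage were not tested here.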

How the results depend on the processing

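Library totals without TMM factors, halved counts and the record of each list's call were chosen after seeing the data, and the other alternatives before.

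Of 301 values of named genes, 281 kept their direction and side of the threshold under all alternatives run on them. Over 6261 values under alternatives, 6192 did so, 43 were no longer past the threshold, 26 came past it and 0 were reversed, and 12 of the 301 were not past it at first. PKL in pkl against WT was among those that came past it, with log2 values of 0.08 with RLE factors and 0.15 with library totals.

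Counts of genes in the 6 comparisons stayed within 1.5 times under DESeq2, RLE factors, both filters, limma-trend on FPKM, library totals, halved counts and, for the 5 comparisons of 2 groups, only the libraries compared, which gives no interaction. With the 2-fold threshold, which keeps fewer genes by construction, they were 2411, 1375, 2857, 1410, 2069 and 1729 for pkl, pif4-labelled and pklpif4-labelled libraries against WT, the latter against pkl and against the pif4-labelled, and the interaction, and the overlap of the first 2 was 722. Leaving out each library in turn gave 10891 to 11927, 6278 to 7213, 11146 to 12198, 7903 to 8927, 10124 to 11190 and 6528 to 6669 genes, and 3143 to 3558 for the overlap.

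The correlation between backgrounds was 0.321 for pkl and 0.159 for pif4 without a low-count filter, and 0.284 for pif4 with the filter at 5 CPM. Without single libraries it was 0.470 to 0.488 for pkl and 0.233 to 0.254 for pif4. The cause was not tested.

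Lists past the threshold in the pklpif4-labelled libraries against WT were 3 with an estimated correlation in place of 8. By fry, which does not set a list against other genes, they were 18, 19 and 20 in pkl, pif4-labelled and pklpif4-labelled libraries against WT. With halved counts they were 5 in pkl in place of 9, since seed, expansin, flowering and mitotic lists missed the threshold, and the cause was not tested. Without single libraries they were 7 to 10, 10 to 12 and 7 to 9. Photosystem, chlorophyll, jasmonate, glucosinolate and root lists in pkl kept their call in all 17 alternative fits recorded, which do not include the estimated correlation or fry.

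With the filter at 5 CPM, 7 list tests came past the threshold that, with the usual filter, had passed with neither correlation. Given with the genes higher and lower under the usual filter, photosystem genes (10 and 5 of 19, adjusted p = 0.0429) and heat shock genes (8 and 6 of 17, adjusted p = 0.00315) were called higher in the pklpif4-labelled libraries against WT. Against pkl, the abscisic acid list was called higher (4 and 7 of 12, adjusted p = 7.04e-07) and root markers lower (6 and 5 of 16, adjusted p = 0.024), although their medians with the usual filter were -0.41 and 0.05. Against the pif4-labelled libraries, root markers were called lower (4 and 4 of 16, adjusted p = 0.033, median 0.26) and flavonoid genes higher (3 and 1 of 11, adjusted p = 0.033), and flavonoid genes had a positive interaction (2 and 1 of 11, adjusted p = 0.00784).

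Replicate numbers did not pair the libraries, since same-numbered libraries had correlations of -0.027 to 0.020 and 3 of 12 correlated best with their own number. With the replicate block, 11810, 7120, 12072, 8795, 11050 and 7005 genes passed, and 9, 12 and 9 lists. Of list calls, expansins in pkl (adjusted p = 0.141) and stomatal markers in pklpif4-labelled against pif4-labelled libraries (0.0703) missed the threshold, and stomatal markers in pkl (0.049), the clock in pif4-labelled (0.0394) and photosystem genes in pklpif4-labelled libraries against WT (0.031) came past it.

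Depth limits comparisons with a group of few counts, such as AT4G12490 in the pif4-labelled and FUL in the pkl libraries, where ratios have wide counting intervals.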

Other observations

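The neighbour test was planned before its result was seen. The other values were looked at after the results were seen and are described without a test of a cause.

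Genes that lie next to each other changed together in pkl. Across 20207 pairs of adjacent genes without overlap, which are not independent replicates, log2 changes against WT had a Pearson r of 0.0956 (permutation p = 0.001, the smallest that 1000 permutations give, adjusted over 15 tests 0.0025). It was 0.102 in the pif4-labelled and 0.116 in the pklpif4-labelled libraries, so a like value was found in each comparison. All these comparisons share the WT libraries, and neighbour correlation in the WT values would enter each of them. Whether the value is particular to pkl is therefore left open. The hypothesis that changes in pkl spread over domains predicted a correlation of genes 10 places apart above the permuted orders, where r was 0.0019 (permutation p = 0.4, highest permuted value 0.0218). By the prediction as written, this argues against domains that reach over 10 genes with a correlation like that of adjacent ones. At 2 places r was 0.0395 in pkl, 0.0319 in the pif4-labelled and 0.0267 in the pklpif4-labelled libraries (permutation test, adjusted p = 0.0025 in each). At 5 places r was 0.00296 in pkl (permutation p = 0.3), 0.0161 in the pif4-labelled (adjusted p = 0.017) and 0.0141 in the pklpif4-labelled libraries (adjusted p = 0.03). At 20 places r was 0.0160 in pkl (adjusted p = 0.015), 0.0130 in the pif4-labelled (adjusted p = 0.041) and 0.0199 in the pklpif4-labelled libraries (adjusted p = 0.0043). These permutation p-values are one-sided, for higher correlations, and the comparisons share the WT libraries. The small value at 20 places is left open, and weaker links than the test could see may exist. The reading of this test was changed to undecided after its result was seen, and then set back to the one written before.

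AT5G43800.1 was on in WT alone, with 41.5 ± 1.63 CPM against 0.111 ± 0.0894 in pkl, 0 in the pif4-labelled and 0.0174 ± 0.0301 in the pklpif4-labelled libraries. AT4G29200 was highest in pkl, with 42.0 ± 1.13 CPM against 0.0230 ± 0.0258 in WT. AT2G01422 reached 68.4 ± 2.51 CPM in pkl and 68.6 ± 1.51 in the pklpif4-labelled libraries, close to each other.

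Of 69 tested chloroplast genome genes, 15 were lower and 0 higher in pkl against WT, and of 41 mitochondrial genome genes 11 were higher and 0 lower. Among all 22130 tested genes, 5865 were lower and 5993 higher in pkl. Neither the 15 of 69 nor the 11 of 41 exceeded that share, but the calls in each class went in a single direction. Median log2 changes were -0.38 for the chloroplast and 0.60 for the mitochondrial genes. Poly(A) selection leaves few such reads, which made up 0.0138% to 0.0218% and 0.00565% to 0.00889% of the counts. Of 240 tested identifiers not of the plain AGI form, 83 were higher and 34 lower in pkl, and 86 and 39 in the pklpif4-labelled libraries. For all 22130 tested genes these counts were 5993 and 5865 in pkl, and 6009 and 6127 in the pklpif4-labelled libraries.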
